A study of Salmo salar with 16 samples.

How the data were processed

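Gene expression was measured in unfertilised eggs of Atlantic salmon with 1-colour microarrays, 1 array per female, on 16 arrays. Per the labels' protocols, total RNA was amplified and labelled with Cy3 before hybridisation. The authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The processed intensity of each spot in these deposited files is background-subtracted within its array and is not normalised between arrays, per the file headers. The same files give the median intensity of each spot and of its local background, and the flags (other columns, coded as yes or no) that Feature Extraction, per the file headers, set for spots well above background, saturated spots and outlier spots. The authors also deposited a table of log2 values. Every column of that table has a median of 6.57, and in each array the table equals the log2 processed signal plus a constant, with a range of the difference of 4.07e-06 for the array of female 1. Its scale is therefore log2, its centring is the array median and no ratio or direction is involved.

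Females are named by the number in the labels. The labels put 4 females in a control group (females 1, 3, 4 and 6), 3 in a group injected with cortisol (2, 5 and 7), 4 in a group equipped with a cortisol pump (8, 9, 10 and 17) and 3 in a group equipped with a control pump (11, 12 and 15). The labels of 2 further females, 13 and 16, contradict each other: their titles read like those of the cortisol pump females, and their other labels say control pump. These 2 arrays entered no comparison between groups and were placed both ways as alternatives. Each array is the egg batch of a separate female, so p-values measure the spread between females. Cortisol doses, times, the content of the injection and of the control pump, and what the control females received are not given in the sources used here, so the comparison of injection with control can include the injection itself. The array files place the 16 arrays on 4 slides of 4 arrays each.

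For the main values, the log2 processed signal was reduced by the 75th percentile of its array, over 43689 probes that are not control spots. Spots with an outlier flag were left out, 230 of them among the probes tested in the 14 arrays with agreed labels. A probe was tested if it was well above background on at least 3 of the 14 arrays and had at least 2 unflagged spots in every group, which left 36576 probes. Missing spots removed 18 probes. A linear model with 4 group means was fitted to each probe on the 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that all groups shared 1 estimate of the spread. There were 5 contrasts: cortisol injection against control, cortisol pump against control pump, control pump against control, the difference between the 2 cortisol effects, and their mean. A probe passed at a Benjamini-Hochberg adjusted p under 0.05. These tests, the groups and the list of alternatives were fixed before the data were examined.

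The fit was tested on simulated data with the means, spreads and group sizes of the 36576 probes. In each comparison 67 probes were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The noise was normal and independent between probes and arrays, with no slide effect and no array that stands apart. The shares recovered therefore need not hold for the real data. For cortisol injection against control, it recovered 16.4% of probes changed 2-fold and 75.8% of those changed 4-fold. For cortisol pump against control pump these shares were 37.3% and 74.2%, and for control pump against control 23.9% and 80.3%. Of probes changed 1.5-fold, it recovered 0%, 0% and 2.99% in the same order. Unchanged probes that passed numbered 7, 4 and 2. The number of arrays limits the precision of all comparisons.

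The 43689 probes are identified in the files by 23278 clone positions, 19956 cluster numbers, 409 sequence accessions and 46 array design numbers. Of the sequence accessions, 112 are RefSeq accessions. In a text comparison, no identifier matched the table of salmon RefSeq genes used here (assembly Ssal_v3.1). Whether a difference in how accessions are written hid matches was not tested. So 0 probes have a gene name here, and the files do not pair the identifiers with names. The rule fixed for naming genes (the probes with a named gene and the lowest p, 12 in each direction or 10 in all) and 18 fixed gene lists, among them markers of follicle cells, blood cells, leukocytes and connective tissue, could not be applied. Probes given by identifier are those with the lowest p in each direction, chosen after the data were seen.

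The shares of variance between groups and between slides are shares of the summed squared distances between arrays, tested by exact permutation over all assignments of the arrays to sets of the same sizes with Python 3.11.15 and numpy 2.4.6. The correlation of the 2 cortisol effects was tested by exact permutation of the labels within each route. Alternatives covered the scaling of the arrays, quantile normalisation, the authors' log2 table, the filter on dim probes, slide as a fixed or a random block, fits on the compared groups alone for the 3 comparisons of 2 groups, array weights, the variance model, a minimum fold of 1.5, both placements of females 13 and 16, and leaving out each female. A planned correction of the background with normexp (offset 50) used the median spot intensity, because the scanner files used here hold no mean. That setting, the fits without slide 2, and the slide block without female 9 were chosen after the data were seen. So were the shares of variance and the correlation, with all their alternatives, and the numbers of 2-fold probes without females 9 and 15.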

Results

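The transcripts of unfertilised eggs from 16 Atlantic salmon females were measured on arrays of 43689 probes. The labels name 2 maternal treatments with cortisol, the main stress steroid of fish. Eggs of cortisol-injected females were compared with eggs of control females, and eggs of females with a cortisol pump with eggs of females with a control pump. The 75th percentile of the processed signal ranged from 491 in female 17 to 955 in female 1, and no probe was saturated on any array.

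Eggs held a broad set of transcripts. Of the 43689 probes, 30878 (70.7%) were well above background in all 14 females with agreed labels, and 4407 (10.1%) in none of them. Probes named by clone position were detected in all 14 females more often (79.3%) than probes named by cluster number (61.3%) or by sequence accession (40.3%). Per array, the detected share was 78.9% ± 3.55 (SD, n = 4) in control females and 80.3% ± 1.99 (SD, n = 3) after cortisol injection. It was 78.3% ± 1.67 (SD, n = 3) with the control pump and 79.0% ± 3.54 (SD, n = 4) with the cortisol pump. The cortisol pump mean includes female 9, at 84.2%.

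**Figure D1:**
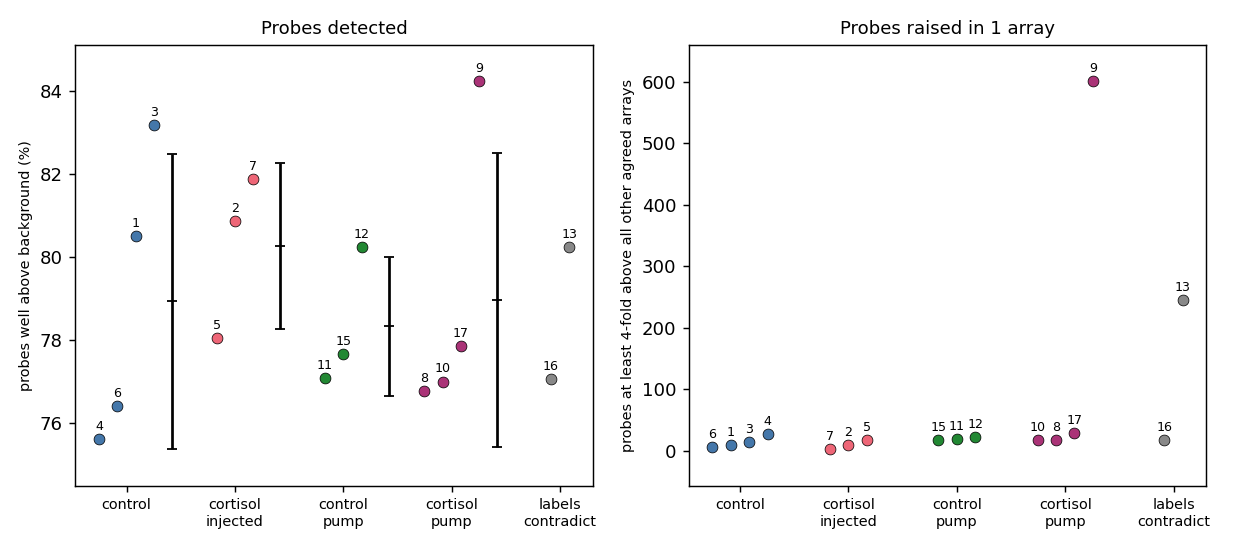
Share of probes well above background in each array (left, percent; the axis does not start at 0) and number of probes at least 4-fold above every other array with agreed labels (right). Points are arrays numbered by female, coloured by group; black bars on the left are group means with SD. Female 9 reached 84.2% detected probes and 601 probes on the right; the other arrays with agreed labels had at most 29.

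The egg profiles were alike across females, and arrays of the same treatment were no more alike than arrays of different treatments. The mean correlation across probes was 0.959 ± 0.0200 (SD) over the 18 pairs of arrays from the same group and 0.961 ± 0.0185 (SD) over the 73 pairs from different groups. Treatment groups accounted for 20.4% of the variance between the 14 arrays, with an exact permutation p of 0.706. With the group labels permuted within slides, the exact p was 0.525. Slides accounted for 33.1% of the variance (exact permutation p = 0.0165), and without female 9 for 30.6% (exact permutation p = 0.0899). A limma F test over slides passed 232 of 36370 probes, with 5822 at an unadjusted p under 0.05. With the treatment group in the model it passed 0, with 6239 unadjusted. A limma F test over groups passed 0, with 1239 unadjusted, and 0 with slide in the model, with 2491 unadjusted.

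**Figure D2:**
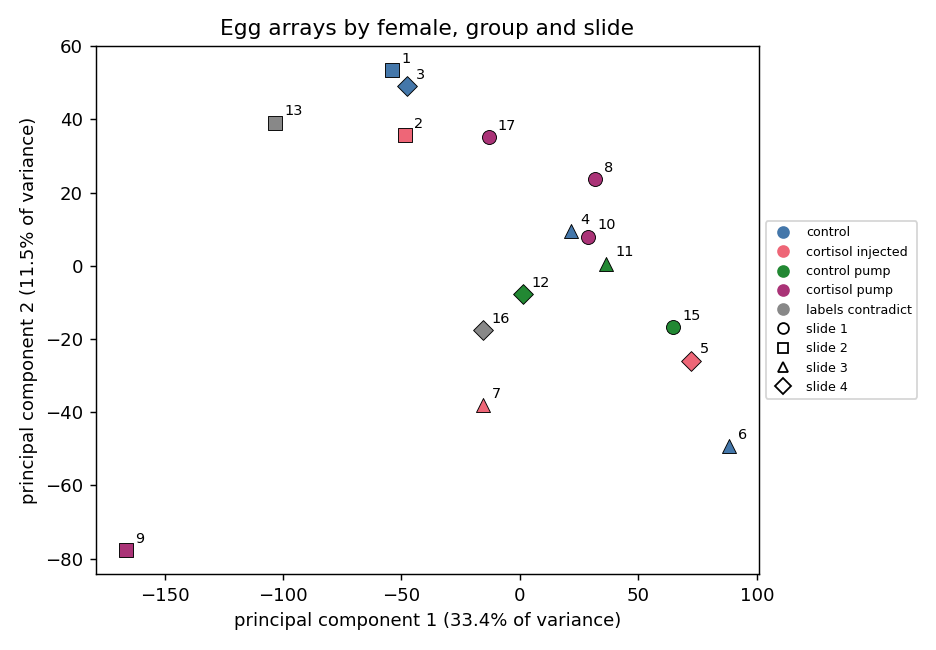
First 2 principal components of the 14 arrays with agreed labels, which carry 33.4% and 11.5% of the variance, with females 13 and 16 projected onto them. Colour gives the treatment group, marker shape the slide, and the number the female. Female 9 lies at the far left, at -166 on component 1, and the colours do not form separate sets.

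Eggs of cortisol-injected females were compared with eggs of control females to find transcripts that differ after injection. No probe passed in limma at an adjusted p under 0.05, and the lowest adjusted p was 0.484. At an unadjusted p under 0.05 there were 674 probes, 344 higher and 330 lower after injection, where 5% of the probes tested is 1829. Other splits of the same females into sets of these sizes gave a median of 942. The 95% confidence interval of the difference lay within 2-fold for 26366 of the 36576 probes (72.1%). The probe with the lowest p was CLUSTER_ID#5430224. Its log2 level was -7.38 ± 2.01 (SD, n = 3) in injected females and -1.09 ± 0.974 (SD, n = 4) in controls, a difference of -6.28 (SE 0.896, limma adjusted p = 0.484). It was well above background in 1 of 3 injected and 4 of 4 control females, so that 2 of the injected values, -8.29 and -8.77, were not well above it and the difference has no exact size. With normexp and quantile normalisation the difference was -1.96 (limma adjusted p = 1). Within slides 2, 3 and 4, the difference was -4.12, -8.29 and -5.83. Among probes higher after injection, CLUSTER_ID#5640604 had the lowest p, with a log2 level of -1.96 ± 1.07 (SD, n = 3) against -4.68 ± 0.967 (SD, n = 4). Its difference of 2.72 (SE 0.579) had a limma adjusted p of 1, and within slides 2, 3 and 4 it was 3.64, 1.14 and 3.73. It was 1.12 with normexp and quantile normalisation. Injected females 2 and 5 read -1.42 and -1.26 in this probe. Injected female 7, at -3.19, was near control female 6 (-3.25) and the control pump females (-3.43, -3.195 and -3.45). The other control females lay between -5.40 and -4.99. On all 3 of these slides, 440 probes differed by at least 2-fold, 125 of them in 1 direction throughout (34 higher, 91 lower); independent directions would give 110. The count of 0 depended on single females: without control female 6, limma passed 25 probes, all lower after injection, with 1205 at an unadjusted p under 0.05, and without injected female 2 it passed 1, CLUSTER_ID#5430224, at an adjusted p of 0.0323. With slide as a fixed block it stayed at 0.

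Eggs of females with a cortisol pump were compared with eggs of females with a control pump to find transcripts that differ with the cortisol. Again no probe passed in limma (lowest adjusted p 0.451). The unadjusted p was under 0.05 for 2324 probes, 418 higher and 1906 lower with cortisol, where 5% of the probes tested is 1829. Other splits of the same females into sets of these sizes gave a median of 1952.5. By size alone, 1537 probes were at least 2-fold higher and 567 at least 2-fold lower, without regard to error. Without female 9 these numbers were 785 and 740, without female 15 they were 1256 and 771, and without both 682 and 1083. The 95% confidence interval lay within 2-fold for 67.2% of probes. The probe with the lowest p was 9_4_3_23, with a log2 level of -4.03 ± 0.254 (SD, n = 4) with cortisol and -5.29 ± 0.185 (SD, n = 3) with the control pump. The difference was 1.25 (SE 0.178, limma adjusted p = 0.451), and 1.36 within slide 1, which alone holds both groups. It was 0.285 with normexp and quantile normalisation. Among lower probes, CLUSTER_ID#5682619 had the lowest p, with log2 levels of -6.03 ± 0.224 (SD, n = 4) and -4.93 ± 0.363 (SD, n = 3). Its difference was -1.10 (SE 0.194, limma adjusted p = 0.778), and -0.963 within slide 1. With normexp and quantile normalisation it was -0.193. The probe was well above background in 3 of 4 females with the cortisol pump. With slide as a fixed block, 2 probes passed, both higher with cortisol, with log2 differences of 2.23 and 3.31 (limma adjusted p = 0.0216 and 0.0268), against 1.25 and 1.70 without the block. Both were low in female 15, the only control pump array on slide 1, and not in the other control pump females, and both were highest in female 9 (-1.64 and -1.89), the only cortisol pump array off slide 1. The first probe had a log2 level of -5.72 there, against -3.25 and -3.47 in the other control pump females and between -3.46 and -3.20 in cortisol pump females 8, 10 and 17. The second had -8.54 there, not well above background, against -4.66 and -4.68 in the other control pump females and between -5.52 and -4.61 in those cortisol pump females. Without the block, the 2 differences were 0.83 and 0.911 without female 9, and 0.0447 and -0.381 without females 9 and 15. With the block, the unadjusted split was 1477 higher and 2130 lower. With the block and without female 9, limma passed 141 probes. All cortisol pump females then lie on slide 1, with female 15 as its one control pump array. Without the block, limma passed 1 probe without cortisol pump female 8, and 2 without control pump female 12.

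**Figure D3:**
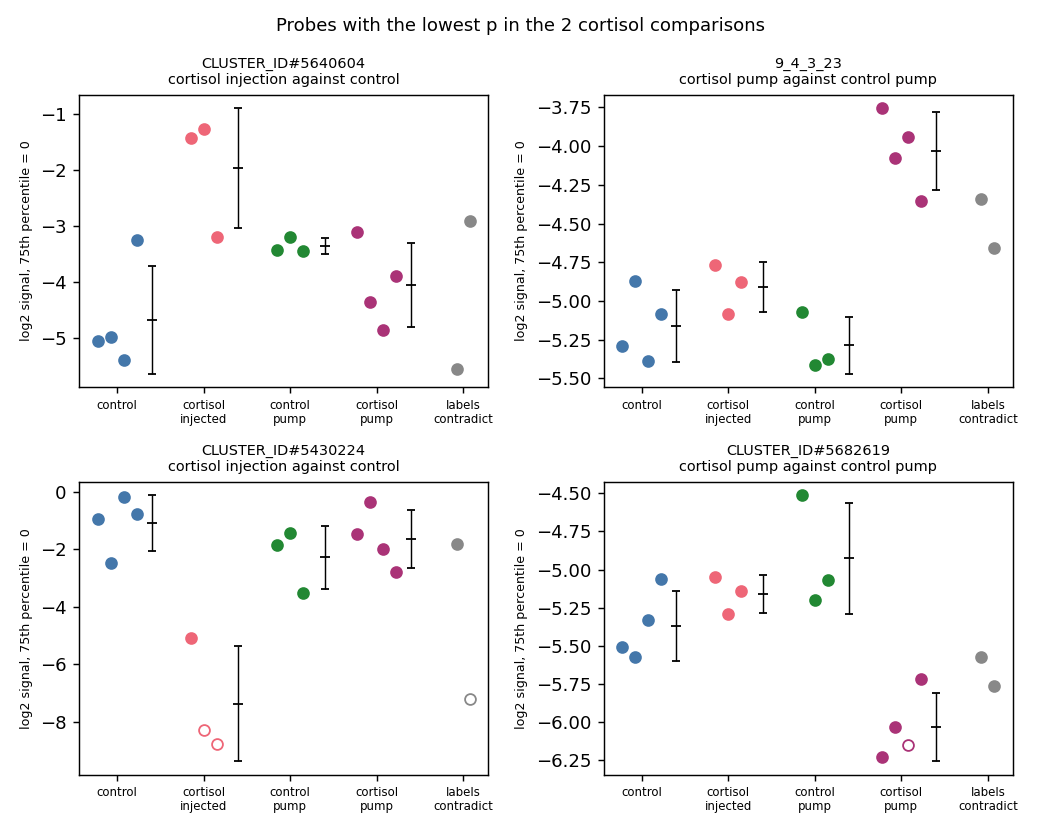
Log2 signal, relative to the 75th percentile of each array, of the probes with the lowest p among higher (top row) and lower (bottom row) probes, for cortisol injection against control (left) and cortisol pump against control pump (right). Points are arrays (open where the probe was not well above background); black bars are group means with SD. For CLUSTER_ID#5430224, at the lower left, injected females lie between -8.77 and -5.07 and control females between -2.46 and -0.169.

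Eggs of females with a control pump were compared with eggs of control females, as a measure of the difference between both kinds of control. In limma 0 probes passed (lowest adjusted p 1), with 1111 at an unadjusted p under 0.05, of which 629 were higher and 482 lower with the pump. The 95% confidence interval lay within 2-fold for 70.1% of probes. The lowest p belonged to a probe whose log2 level was -6.35 ± 0.248 (SD, n = 3) with the control pump and -3.13 ± 0.67 (SD, n = 4) in control females. Its difference was -3.21 (SE 0.588, limma adjusted p = 1), and -2.87 and -3.36 within slides 3 and 4. It was well above background in 1 of 3 females with the control pump, so that the difference has no exact size. The difference was -0.822 with normexp and quantile normalisation, and -1.46 with females 13 and 16 placed in the control pump group by their source names. Among higher probes, the lowest p went with a difference of 1.03 (SE 0.193, limma adjusted p = 1), and 1.15 and 1.01 within slides 3 and 4. On both slides, 772 probes differed by at least 2-fold, 313 of them in the same direction (142 higher, 171 lower), where independent directions would give 386. Without control female 6, limma passed 13 probes, 1 higher and 12 lower, with 2104 at an unadjusted p under 0.05.

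Whether the 2 routes changed the same transcripts was tested on the difference and on the mean of the cortisol effects. For the difference, limma passed 0 probes (lowest adjusted p 0.947), with 1588 at an unadjusted p under 0.05, 1181 of them with a larger signed effect of injection than of the pump and 407 with a smaller one. The median difference over all probes was 0.10 on the log2 scale with the 75th percentile as reference. Scaled to the array median, the unadjusted split was 762 and 479. For the mean effect limma also passed 0 (lowest adjusted p 1), with 990 at an unadjusted p under 0.05, 312 higher and 678 lower. With slide as a fixed block both stayed at 0, with 2971 unadjusted for the difference (1830 larger, 1141 smaller) and 1981 for the mean (996 higher, 985 lower). Across probes, which are not independent replicates, the correlation of the 2 cortisol effects was 1.885e-06. Relabelling the females within each route gave values from -0.593 to 0.579 (exact permutation p = 1). The routes share no females. Without control female 6, limma passed 4 probes for the difference, with 2517 at an unadjusted p under 0.05, and 1 for the mean. Without injected female 5, 946 probes had an unadjusted p under 0.05 for the difference, and none passed. Without injected female 7 it passed 1 for the difference, and without cortisol pump female 8 it passed 1 for each.

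**Figure D4:**
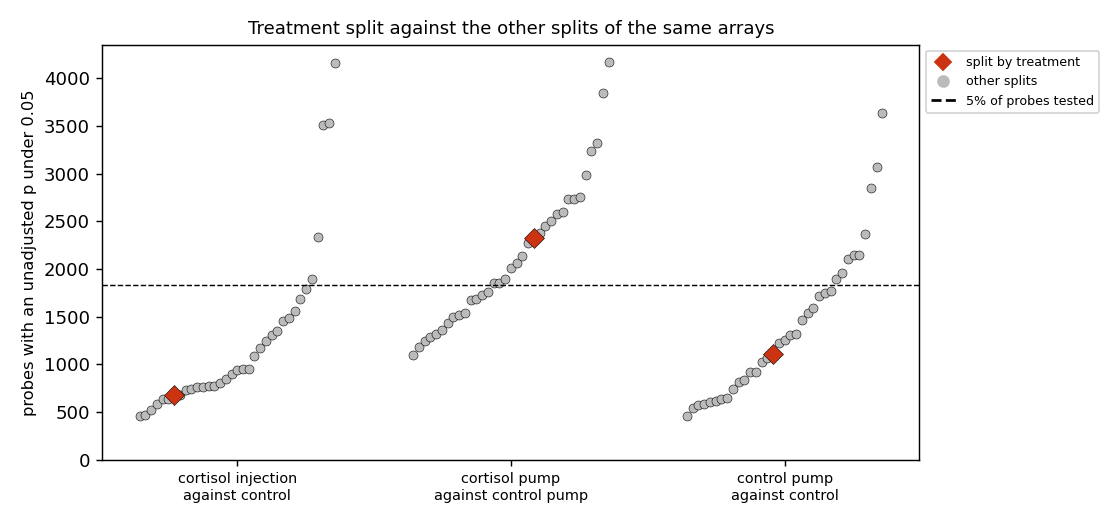
Number of probes with an unadjusted limma p under 0.05 for the split of the females by treatment (red diamonds) and for the other splits of the same arrays into sets of the same sizes (grey points), in 3 comparisons. The dashed line is 1829 probes, 5% of those tested. The split by treatment gave 674, 2324 and 1111 probes, and other splits reached 4154, 4166 and 3637.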

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

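The tests of a brighter array and of treatment groups, the look at slide 4 for the raised probes, and the exchange of labels within slides were chosen only after the results they bear on had been seen; the counts of other splits, with and without slide as a block, the test of slides without female 9 and those of slide 2 and of female 13 for the raised probes were set before, with the count of raised probes in female 13 already known and, for the splits with the block, the real counts and the splits without it. A female far from the others was sought in 18 sets of values, each from the 4 females of the control or the cortisol pump group. Of these, 4 held one, where chance gives about 1 in 20. The sets share females, and several far values belong to female 9, so they are not independent.

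Female 9 stood apart from the rest of the cortisol pump group, all on slide 1, in 3 measures. Its share of detected probes, 84.2%, was the highest of its group, the next being 77.8%. In other groups, control female 3 reached 83.2% and injected female 7 reached 81.9%. Its median correlation with the other arrays, 0.920, was the lowest of its group, the next being 0.966. Outside the group, control female 6 had 0.962 and female 13 had 0.933. In female 9, 601 probes were at least 4-fold above every other array with agreed labels, against at most 29 in any other. Female 13, whose labels contradict each other, had 246 such probes, against at most 28 in the control and control pump females. The probe with the lowest p for control pump against control was far lower in control female 6 (log2 -4.14) than in the other control females, the next being -2.85.

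The 601 probes of female 9 were followed into the other arrays. A brighter array is not the cause by itself: the array of female 1 was brighter (955 against 723 at the 75th percentile) and had 9 such probes. In female 13, which was not used to choose them, the same probes lay a median of 2.30 (log2) above the median of the other 13 agreed arrays, and 80.9% of them were at least 2-fold above it. That is consistent with a source of RNA that eggs of other females can share, as a hypothesis. Females 9 and 13 lie on the same slide; there, females 1 and 2 exceeded the other slides by a median of 1.07, but female 3 (0.91) and female 16 (1.09), on slide 4, were as high as females 1 (0.93) and 2 (0.89), while females 5 (-0.65) and 12 (0.18) of slide 4 were not raised, so a part played by the slide stays open, and the cell markers that could name a tissue could not be tested.

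Arrays of 1 slide resembled each other more than arrays of 1 treatment group. Treatment is not the whole of this: with slide labels permuted within treatment groups, the share of variance between slides still had an exact p of 0.0272. Without female 9 the exact permutation p was 0.0899, which lies between what the slides and what female 9 alone would give, so these cannot be told apart with 14 arrays.

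Spiked control RNA, relative to the 75th percentile of each array, was 3.63 (log2) in female 10 and 4.28 in female 17. Both had the cortisol pump and lie on slide 1, as do females 8 and 15. It was 2.48 in injected female 2, against at most 2.21 in the control and control pump females. Injected female 7 (2.33) and cortisol pump female 8 (2.32) were slightly above 2.21, and injected female 5 (2.11) and cortisol pump female 9 (1.78) below it. These means leave out the spike probes E1A_r60_3 and E1A_r60_a104. E1A_r60_3 was hardly raised, at -1.93 in female 10 and -1.77 in female 17, against -1.88 in control female 4. E1A_r60_a104 was raised, at -7.01 and -6.19 against -7.97.

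Chance could not be excluded for any of the 5 counts at an unadjusted p under 0.05 in splits that ignore slide. For cortisol injection, 29 of the 35 splits of the 7 females gave at least the 674 probes of the real split, and the highest other gave 4154. For the cortisol pump, 14 of 35 gave at least 2324 (highest other 4166), and for the control pump against control, 20 of 35 gave at least 1111 (highest other 3637). For the difference of the 2 effects, 36 of 100 drawn splits gave at least 1588 (highest other 7723), and for their mean, 81 of 100 gave at least 990 (highest other 4047). Splits that follow a slide exceeded the real ones: slide 3 against the rest gave 2330 probes among the injection arrays and 1748 among the control and control pump arrays, and slide 1 against the rest 3845 among the pump arrays. The highest counts in these comparisons, 4154, 3637 and 4166, came from splits that follow no slide. The split of females 4, 5, 6 and 7 against 1, 2 and 3 passed 473 probes after adjustment in limma, the most of the 34 other splits, where the real split passed 0. The 601 raised probes described above part the same sets. Over the median of the other agreed arrays, their median log2 was 0.93, 0.89 and 0.91 in females 1, 2 and 3. It was -0.17, -0.65, -0.805 and 0 in females 4, 5, 6 and 7. Whether the 473 probes overlap with the 601 was not tested, and the source of the split stays unknown. Females 4, 6 and 7 are all the slide 3 arrays of that comparison, but slide 3 against the rest passed 1 probe after adjustment, so slide 3 alone does not give the 473.

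With slide as a fixed block the 5 counts were 986, 3607, 1239, 2971 and 1981, in the same order. Chance could not be excluded for 4 of them: 27 of 35 splits gave as many for injection (highest other 4096), 22 of 35 for the control pump (highest other 3199), 11 of 98 for the difference (highest other 6053) and 39 of 98 for the mean (highest other 4660). For the cortisol pump the real split alone, 1 of 34, reached 3607 (highest other 3134), a share under 0.05 in 1 of these 5 blocked counts. These splits move females between slides, so that the block takes up a different part of each; labels exchanged within slides avoid that. Then the arrangements were too few for a share under 0.05 for the cortisol pump (1 of 4 gave 3607, highest other 2903), for injection (9 of 12 gave at least 986, highest other 3486) and for the control pump (4 of 6 gave at least 1239, highest other 2244). Chance could not be excluded for the difference, with 6 of 48 (highest other 5814), or for the mean, with 26 of 48 (highest other 4660). The cortisol pump and its control meet on slide 1 alone, in female 15 against females 8, 10 and 17, so a part played by female 15 in the blocked count stays open.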

How the results depend on the processing

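The counts of 0 probes held in all 5 comparisons under each scaling, quantile normalisation, both filters on dim probes and slide as a random block. They held under array weights, the trend and robust variance model and both placements of females 13 and 16. They also held in fits on the compared groups alone, run for the 3 comparisons of 2 groups. The authors' table gave 0 as well, but it repeats the scaling to the array median up to a constant per array. A minimum fold of 1.5 only filters probes that passed, so it could give nothing but 0. Slide as a fixed block gave 2 probes for the cortisol pump against its control and 0 for the others. Leaving out 1 female gave 0 to 25 probes for injection, 0 to 2 for the cortisol pump, 0 to 13 for the control pump, 0 to 4 for the difference of the effects and 0 to 1 for their mean. Added after the data were seen, normexp with quantile normalisation and the fits without slide 2 gave 0 throughout. Slide as a block without female 9, also added then, gave 141 for the cortisol pump, 14 for the difference, 22 for the mean and 0 for the others; all cortisol pump females then lie on slide 1, with female 15 as its one control pump array, and that female had 78 probes at least 4-fold below every other agreed array. The cause of the other changes was not tested. Array weights raised the unadjusted count of the control pump against control from 1111 to 3025 and that of injection from 674 to 1764. The log2 differences of the 6 probes with the lowest p in each direction, for the 3 comparisons of 2 groups, kept their sign. These probes were picked by their p in the same arrays, so a kept sign says little. Normexp with quantile normalisation, whose offset compresses dim signals, made each of the 6 smaller, such as -1.96 for -6.28 and 0.285 for 1.25. The 2 probes that passed with the block were otherwise recomputed only without female 9, female 15 or both; without both, the second turned from 1.70 to -0.381. The shares of variance and the correlation, with their alternatives, were added after the data were seen. The share between slides ranged from 30.6% to 36.5% without 1 female and passed the threshold except without female 9 (30.6%); that between groups, from 19.6% to 24.9%, never did. The correlation of the 2 effects, near 0, turned to -0.0106 on probes detected in all 14 arrays and ranged from -0.19 to 0.262 without 1 female. Probes detected in all females numbered 30751 to 35229 under the alternatives. The alternatives for gene lists were not run, because no probe has a gene name here. For dim probes, signal over background limits the differences that can be measured.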

Other observations

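The test of shared splits below was chosen after its result had been seen; that of continuous differences was set before.

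Some probes parted the females into a high and a low set with a wide gap between them. In 59 of 36353 probes, the 14 females with agreed labels fell into 2 sets of at least 3 females each with a gap of at least 8-fold between them. In 31 of the 59, no female of the lower set was well above background. The largest gap, 8.98 on the log2 scale, was in a probe with 8 females low and 6 high. The next, 7.03, was in a probe with 10 low and 4 high. In both, no low female was well above background, so these gaps have no exact size.

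The tables argue against 1 cause shared by all these probes. The 59 probes split the females in 53 different ways, and at most 3 probes shared a split. In 0 of them did the split set 1 treatment group or 1 slide against all other females. Splits that join groups or slides, such as both cortisol groups against both others, were not checked. Values drawn from a normal distribution with the SD of each probe gave 4.3 such probes on average, so differences of that shape do not account for their number. Continuous differences of another shape were not simulated. In 31 of the 59 probes the lower set was not well above background, which the simulation did not include, so continuous differences stay open. A candidate explanation is that females carry different forms or copies of single genes, which the arrays read as present or absent in their eggs. No genotype was used here, so this was not tested.

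For the 2 females with contradictory labels, values were as follows. Female 13 had 80.2% of probes well above background and a median correlation of 0.933 with the 14 other arrays, and female 16 had 77.1% and 0.969. The probe CLUSTER_ID#5430224, low in the injected females, read -1.80 (log2) in female 13 and -7.21, not well above background, in female 16. Female 15, with the control pump, had 78 probes at least 4-fold below every other array with agreed labels, against at most 18 in any other array.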
